A study of Mus musculus with 2 samples.

How the data were processed

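Chromatin immunoprecipitation with sequencing (ChIP-seq) for CTCF, a zinc finger protein that binds insulators and the anchors of chromatin loops, was made on livers of B6NCrl mouse embryos at day 14.5. Per the labels, the livers were pulverised and pooled from several dissections and from both sexes. The 2 libraries form 1 group and come from 1 biosample, although the labels number them as biological replicates. Their spread was therefore taken to cover library making and sequencing rather than variation between animals, which could not be checked. All errors given as mean ± SD with n = 2 are of this kind.

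Per the file headers and the deposited text files, the peak lists are narrowPeak tables on mouse build mm10, called on alignments with a control. The authors deposited 1 list for each replicate, 1 for both replicates pooled, and a pair of lists thresholded by the irreproducible discovery rate (IDR), named optimal and conservative, which were derived from the pooled list and both replicates' lists. The peak caller is not given in the sources used here. The deposited signal of a peak is the caller's own value on a relative scale that is not stated, and it was larger in the pooled list than in each replicate's list, so signals were compared only within a list. The deposited lists also give the -log10 of the q value, which was capped at 4.90 in the optimal list and was not used. The deposited score of the optimal list ran from 537 to 1000, with 79.4% of peaks at 1000, and was not used. The last column in the deposited files is the summit as an offset in bases from the start of the peak. The control, the fold-change tracks and the p-value tracks were not analysed here.

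The number of reads per library is unknown. What the files show is the number of peaks. It was 300000 in the list of each replicate and in the pooled list. The optimal list held 50909 and the conservative list 49129. The equal length of the lists of 300000 carries no information on depth or on differences between the libraries. Wilson 95% intervals are given for shares of peaks and cover counting error only. Pooled and thresholded lists are single values with no replicates. The replicate error therefore comes from the same measurement on the 50909 strongest peaks of each replicate, as many as the optimal list holds.

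Peaks were placed by their summits on the reference genome and on GENCODE annotation vM21. A summit within 1 kb of an annotated transcript start was called promoter, and any other was called exon, intron or intergenic, in that order. Location shares were compared with 100 random placements of the summits on the same chromosomes outside assembly gaps, by a 2-sided permutation test whose smallest p is 0.02. The core CTCF motif was written as CCASYAGRKGGCRS, searched on both strands within 50 bp of the summit with at most 2 mismatches, and compared with windows moved by 1 kb through Fisher's exact test. Neighbouring peaks with a motif, 20 kb to 1 Mb apart, were called convergent when their motifs pointed to each other, and were compared with 1000 shuffles of the strands within chromosomes. Peak signal on X was compared with 1000 draws of as many autosomal peaks. The smallest p of these shuffles and draws is 0.002, and all tests were 2-sided.

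For 13 gene lists, the share of genes with a promoter peak was compared with all other protein-coding genes by Fisher's exact test with Benjamini-Hochberg adjustment over the lists. For 23 loci, peaks were counted between the outer ends of the named genes with 50 kb on each side, without a test. Replicate peaks were called shared when their summits lay within 100 bp, against a chance level from summits moved by 10 kb. The relative signal of a named peak is the signal of the replicate's own peak within 100 bp of the optimal summit, divided by the median signal of that replicate's 50909 strongest peaks.

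The comparisons, motif, lists, loci, threshold of 0.05 and most alternatives were chosen before the data were examined. So was the rule for naming peaks, which takes the 10 optimal peaks of highest signal, the strongest peak of each locus, and in each list the 3 genes with the strongest promoter peaks. Relative signals are printed for some of the genes and peaks this rule takes, and others are only named or counted. Of the genes it takes, 1 is not reported here. The alternatives were the conservative list, optimal peaks above the median signal, each replicate alone, other summit distances, other numbers of strongest peaks, other promoter windows, other motif settings, other neighbour distances, narrower loci and the mean signal. Alternatives added after the data were seen were leaving out peaks ranked beyond 100000 in the pooled list, 1 transcript start per gene, and promoter peaks with a motif match only. GC content was measured within 100 bp of summits and within 500 bp of gene starts, and matched in bins of 5 points. Peaks on unplaced scaffolds, 21 in the optimal list, were left out of every comparison of locations, motifs, genes and chromosomes. The steps were tested on simulated data, where a planted promoter share of 33.1% was measured as 33.0% and a planted motif share of 60.0% as 60.0%. Planted promoter summits lay within 1 kb of starts of the same annotation, so their recovery was nearly fixed in advance. The simulated motif matches were placed at the summits, so the search of the genome for the motif was not tested. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.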

Results

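CTCF binding was mapped in the liver of mouse embryos at day 14.5, when the organ is a main site of red blood cell formation. The optimal list held 50909 peaks, the conservative list 49129, and the list of each of the 2 replicates 300000. Read depth is unknown. All positions are on build mm10, and the processing above defines relative signal.

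The 10 strongest optimal peaks show what the highest occupancy looked like. The peak of highest signal lay on chromosome 5 at 120102729 to 120103160, in intergenic sequence 13510 bp upstream of a start of Rbm19, with a signal of 747 and a relative signal of 11.2 ± 2.29 (SD, n = 2). The next lay in the 5' UTR of Acbd4 on chromosome 11 at 103102619 to 103103103, with a signal of 725 and a relative signal of 11.0 ± 1.99 (SD, n = 2). An intron of Fam129b on chromosome 2, at 32912366 to 32912808, held the third, with a signal of 714 and a relative signal of 10.9 ± 2.13 (SD, n = 2). Peaks nearest to starts of Epm2aip1, Comtd1, Pink1, Iqsec1, 4930509E16Rik, Polr3gl and Armc9 completed the 10, down to a signal of 672. All 10 had a motif match, 4 of them without a mismatch, and all ranked among the 30 strongest peaks of both replicates.

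The question of how far the libraries give the same peaks was asked first. Of the 50909 strongest peaks of replicate 1, 40078 had a summit of replicate 2's strongest peaks within 100 bp, or 78.7% (Wilson 95% interval 78.4 to 79.1), against 1.01% by chance. Across the 47605 optimal peaks with a peak in both replicates' lists, log2 signal had a Spearman's rho of 0.843 and a Pearson's r of 0.825, and peaks are not independent replicates. With 2 times as many peaks from each replicate, the shared percentage was 52.2%, so it is a statement about the strongest peaks. Of each replicate's 50909 strongest peaks, those with none of the other's within 100 bp are called peaks of that replicate alone. The other replicate's full list of 300000 was not searched for them, so some may be present there at a lower rank. Peaks of replicate 1 alone lay at promoters in 38.5% of cases and had a motif match in 28.6%. Those of replicate 2 alone lay at promoters in 12.8% and had a match in 64.4%.

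The optimal and conservative lists overlapped without either containing the other. Of the optimal peaks, 43970 had a conservative summit within 100 bp, or 86.4% (Wilson 95% interval 86.1 to 86.7). The 6939 optimal peaks outside the conservative list had a median signal of 20.4, and the 5159 conservative peaks outside the optimal list had 19.4, against 84.4 for peaks in both.

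CTCF summits were concentrated at gene starts and sparse between genes. Promoters held 20.3% of optimal summits (10349 of 50888, Wilson 95% interval 20 to 20.7), 4.22-fold the 4.82 ± 0.0924% (SD) of random placements, with 20.5 ± 3.87% (SD, n = 2) in the replicates. Intergenic sequence held 34.2%, against 51.4 ± 0.230% (SD) at random, with 34.0 ± 2.5% (SD, n = 2) in the replicates. Introns held 40%, against 40.5% at random, and exons 5.46%, against 3.26%. The promoter and intergenic shares each had a permutation p of 0.02, the smallest that 100 placements can give. The difference between the replicates, 23.2% against 17.7% at promoters, was smaller than the distance of either from the random level. The promoter share was 15.1% with a window of 500 bp and 42.4% with one of 5 kb.

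**Figure D1:**
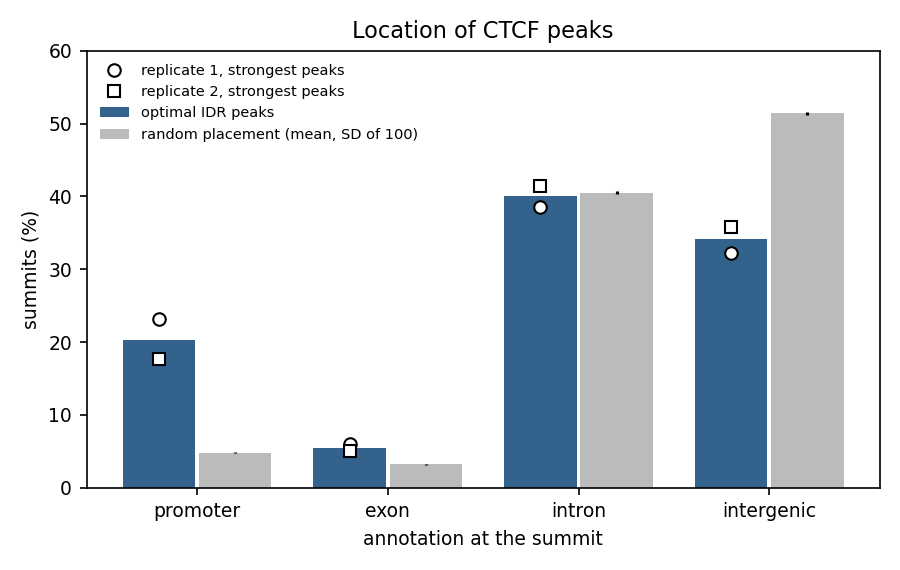
Share of CTCF summits (%, vertical axis) in promoters, exons, introns and intergenic sequence, for the optimal list, both replicates and random placements. Promoters held 20.3% of optimal summits against 4.82% at random, and intergenic sequence 34.2% against 51.4%.

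With up to 2 mismatches allowed, most peaks sat on the CTCF motif, and the strongest did so most often. A match lay near 71.4% of optimal summits (36317 of 50888, Wilson 95% interval 71.0 to 71.8), against 3.44% of windows moved by 1 kb, and near 69.8 ± 6.61% (SD, n = 2) of replicate summits. Promoter peaks had a match in 48.5% of cases, exonic peaks in 70.7%, intronic peaks in 76.1% and intergenic peaks in 79.5%. Peaks with a match free of mismatches had a median signal of 195, peaks with 1 mismatch 102, peaks with 2 mismatches 61.5 and peaks without a match 35.7. The odds ratio of optimal against moved windows was 69.9, with a Fisher's exact p below the floor of 1e-300. This test took each peak and its moved windows as independent and left out their pairing. Peaks are not independent replicates, here and in the Fisher's exact test by signal below. The share depended on the mismatches allowed, at 39.9% with at most 1 and 89.8% with at most 3.

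With optimal peaks put in 5 equal classes of signal, the motif share of the strongest and the weakest class differed by 43.5 points, at 89.1% against 45.6%, with an odds ratio of 9.79 and a Fisher's exact p below the same floor. In the replicates this difference was 42.8 ± 9.95 points (SD, n = 2), and it was 13.9 points when only peaks above the median signal were used and 24.6 points with at most 3 mismatches. Over 10 equal classes of signal, the promoter share was 24.4% in the strongest, 16.0% in the third and 29.8% in the weakest.

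**Figure D2:**
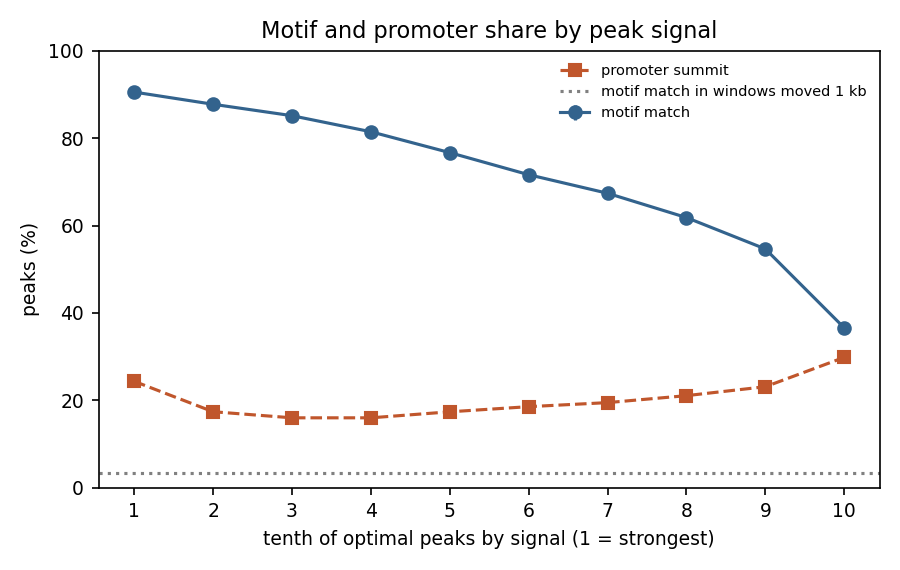
Share of optimal peaks (%, vertical axis) with a motif match (circles, Wilson 95% intervals) and with a promoter summit (squares), in 10 equal classes of signal from strongest to weakest (horizontal axis), and the level in moved windows (dotted line). The motif share was 90.5% in the strongest class and 36.6% in the weakest.

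Motifs of neighbouring peaks 20 kb to 1 Mb apart pointed to each other more often than shuffled strands do. Those of closer neighbours did so less often. Among 19080 neighbouring pairs 20 kb to 1 Mb apart, 27.7% were convergent (Wilson 95% interval 27.0 to 28.3), 22.7% divergent and 49.6% on the same strand, against 25 ± 0.243% (SD) convergent after shuffling. The permutation p was 0.002, the smallest that 1000 shuffles can give, and the replicates gave 27.4 ± 0.0754% (SD, n = 2). With pairs 5 kb to 1 Mb apart, 25.4% were convergent (permutation p = 0.028). A split by distance, chosen after the data were seen, gave 19.5% convergent below 5 kb, 21.2% from 5 to 20 kb, 24.3% from 20 to 50 kb, 28.7% from 50 to 100 kb, 32.7% from 100 to 200 kb and 32.6% from 200 to 1000 kb. Each of these 6 bins had an adjusted permutation p of 0.0024 except the one from 20 to 50 kb, at 0.07. The bins below 5 kb and from 5 to 20 kb held 6318 and 10611 pairs and lay under the shuffled share. The bins above 50 kb lay over it.

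**Figure D3:**
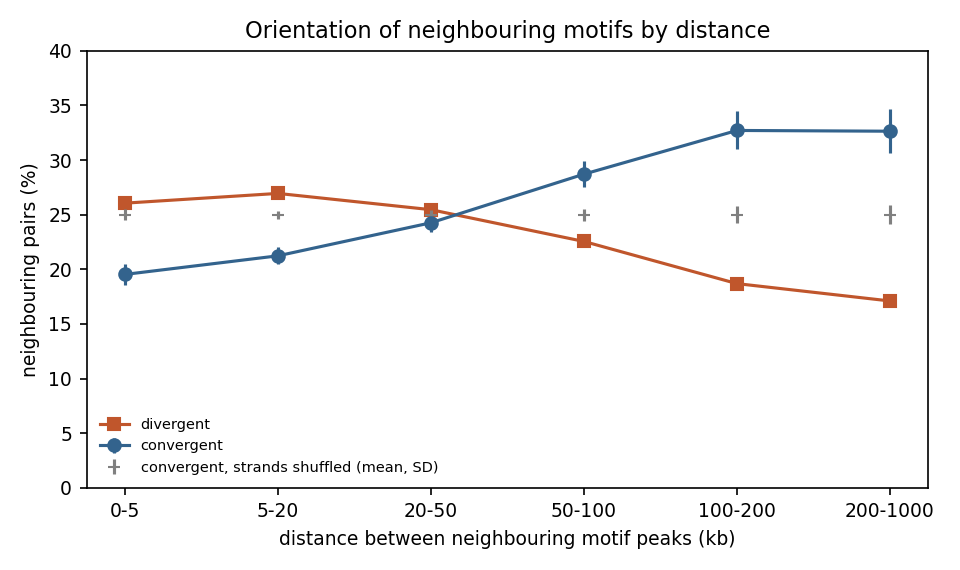
Share of neighbouring motif pairs (%, vertical axis) that were convergent (circles, Wilson 95% intervals) or divergent (squares), by distance in kb (horizontal axis), with shuffled strands as mean and SD. Convergent pairs were fewer than divergent ones below 5 kb, 19.5% against 26.1%, and more frequent from 200 to 1000 kb, 32.6% against 17.1%.

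Gene starts of heme synthesis and iron transport, ribosomal protein, and cohesin and CTCF partner genes held peaks more often than other genes. Those of Hox and olfactory receptor genes did so less often. For short, the heme list and the cohesin list are also called heme synthesis and cohesin genes. Of the heme synthesis and iron transport genes, 14 of 20 had a promoter peak, 70.0% (adjusted p = 0.00779, Fisher's exact test), with 75% in both replicates. Among them were Urod, a heme pathway enzyme, with a relative signal of 6.63 ± 1.52 (SD, n = 2), the mitochondrial carrier Slc25a38 with 4.93 ± 1.20 (SD, n = 2) and Ppox, the penultimate enzyme of the pathway, with 4.06 ± 0.271 (SD, n = 2). Ribosomal protein genes had a peak in 47 of 76 cases, 61.8% (adjusted exact p = 1.83e-05), with strong peaks at Rpl26, at 8.16 ± 1.59 (SD, n = 2), and Rpl36, at 7.75 ± 1.14 (SD, n = 2). Cohesin and CTCF partner genes had one in 15 of 22 cases, 68.2% (adjusted exact p = 0.00842), led by the chromatin remodeller Chd8 at 6.08 ± 1.63 (SD, n = 2), the cohesin acetyltransferase Esco1 at 5.56 ± 1.03 (SD, n = 2) and Maz at 5.17 ± 2.03 (SD, n = 2).

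Hox genes, which pattern the body axis, had a promoter peak in 6 of 39 cases, 15.4% (adjusted exact p = 0.0280). The strongest were at Hoxa7, Hoxb5 and Hoxa10. All 6 had a motif match at their strongest promoter peak, against 48.8% of all protein-coding genes with a promoter peak. In the heme synthesis, ribosomal protein and cohesin lists this share was 42.9%, 42.6% and 53.3%. The peaks named above at Ppox, Chd8 and Maz had no match, and those at Urod, Slc25a38, Rpl26, Rpl36 and Esco1 had one. Olfactory receptor genes had one in 11 of 1134 cases, 0.970% (adjusted exact p = 2.99e-197), with the strongest at Olfr557, Olfr156 and Olfr15. Over all 21911 protein-coding genes the share was 35.2%, and 5 of 13 lists passed the threshold, 3 above and 2 below the other genes.

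The remaining 8 lists did not pass. Erythroid genes had a promoter peak in 17 of 31 cases, 54.8% (adjusted exact p = 0.0789), with the strongest at Zfpm1, a GATA1 cofactor, at 6.18 ± 1.59 (SD, n = 2), the repressor Gfi1b at 5.76 ± 1.08 (SD, n = 2) and Sox6 at 4.09 ± 0.607 (SD, n = 2). Cell cycle genes had one in 54.2%, with the strongest at E2f2, Mcm5 and Mcm2, and imprinted genes in 41.9%, with the strongest at Meg3, Commd1 and Peg13. Neuron and muscle genes had one in 37.5%, with the strongest at Gfap, Ckm and Actn2, and clustered protocadherin genes in 30.4%, with the strongest at Pcdhgb7, Pcdhga12 and Pcdhgb6. Hepatocyte and hepatoblast genes had one in 8 of 30 cases, 26.7%, with the strongest at Apob, Afp and Cebpa. Endothelial and mesenchymal genes had one in 23.8%, with the strongest at Col1a1, Vim and Pdgfra, and other blood cell genes in 20.8%, with the strongest at Vwf, Itga2b and Mpo.

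List calls depended on the replicate and on the way peaks were counted. Replicate 1 alone put 8 lists past the threshold, adding erythroid genes at 61.3% (adjusted p = 0.0261), cell cycle genes at 66.7% (adjusted p = 0.0226) and protocadherin genes at 23.2% (adjusted p = 0.0247), and replicate 2 alone put 4 past it, without the Hox genes (adjusted p = 0.0670), all by Fisher's exact test. With motif-matched peaks only, 1 list passed. The shares were then 40% for heme synthesis (adjusted exact p = 0.0676), 28.9% for ribosomal protein (0.0676) and 36.4% for cohesin genes (0.106), against 18.5% of genes outside these 3 lists. With 1 transcript start per gene, adjusted exact p was 0.107 for heme synthesis, and other blood cell genes passed at 4.17% (adjusted exact p = 0.0253). Erythroid genes also passed among peaks above the median signal, at 41.9% (adjusted exact p = 0.00701), and with a 5 kb window, at 77.4% (adjusted exact p = 0.0344). The call of the Hox genes was also lost with motif-matched peaks (adjusted exact p = 1), above the median signal (0.987), with 1 start per gene (0.230) and with a 500 bp window (0.123). A promoter window of 5 kb ended the call of the cohesin genes (adjusted exact p = 0.0836) and gave Hox genes a peak in 61.5% of cases.

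**Figure D4:**
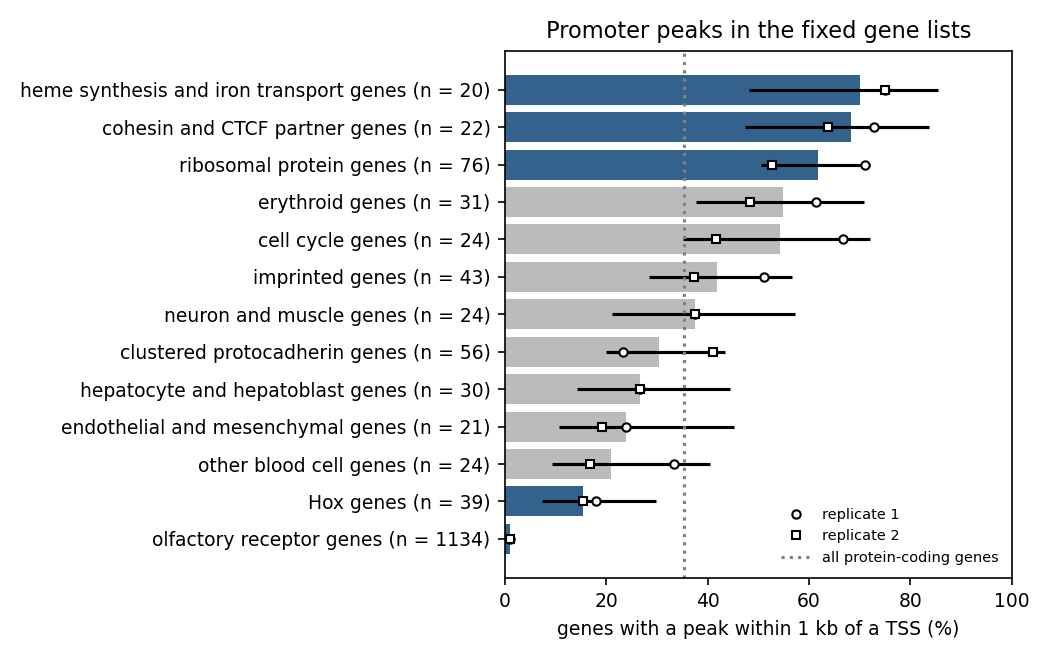
Share of genes with a promoter peak (%, horizontal axis) in each of the 13 lists, for the optimal list (bars, blue where the list passed the threshold, with Wilson 95% intervals) and each replicate (symbols), with the share in all protein-coding genes as a dotted line. Heme synthesis and iron transport genes stood at 70.0% and olfactory receptor genes at 0.970%, against 35.2% for all genes.

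The fixed loci held 219 optimal peaks with 50 kb on each side, and 19 of the 23 were denser in peaks than the genome, at 19.9 peaks per Mb. With 20 kb on each side they held 147, and 20 of the 23 were denser. The loci were drawn around genes, and summits were concentrated at gene starts. No windows around other genes were counted, so these densities do not set the loci apart. The alpha-globin locus, which encodes a chain of haemoglobin, held 15 peaks, or 124 per Mb, with 14.5 ± 2.12 (SD, n = 2) in the replicates. Its strongest peak lay in an intron of Nprl3, the neighbouring gene whose introns carry alpha-globin enhancers, on chromosome 11 at 32238489 to 32238809, with a relative signal of 8.54 ± 2.13 (SD, n = 2). That peak lies beyond the 20 kb flank, within which the alpha-globin locus held 3 peaks, or 49.3 per Mb. The beta-globin locus held 7 peaks, or 49.8 per Mb, and 4 within the 20 kb flank, or 49.6 per Mb. Its strongest peak lay on chromosome 7 at 103806981 to 103807186, 6.92 kb beyond the start of Hbb-bt, with a relative signal of 3.17 ± 1.49 (SD, n = 2) and ranks of 15083 and 4123 in the replicates.

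**Figure D5:**
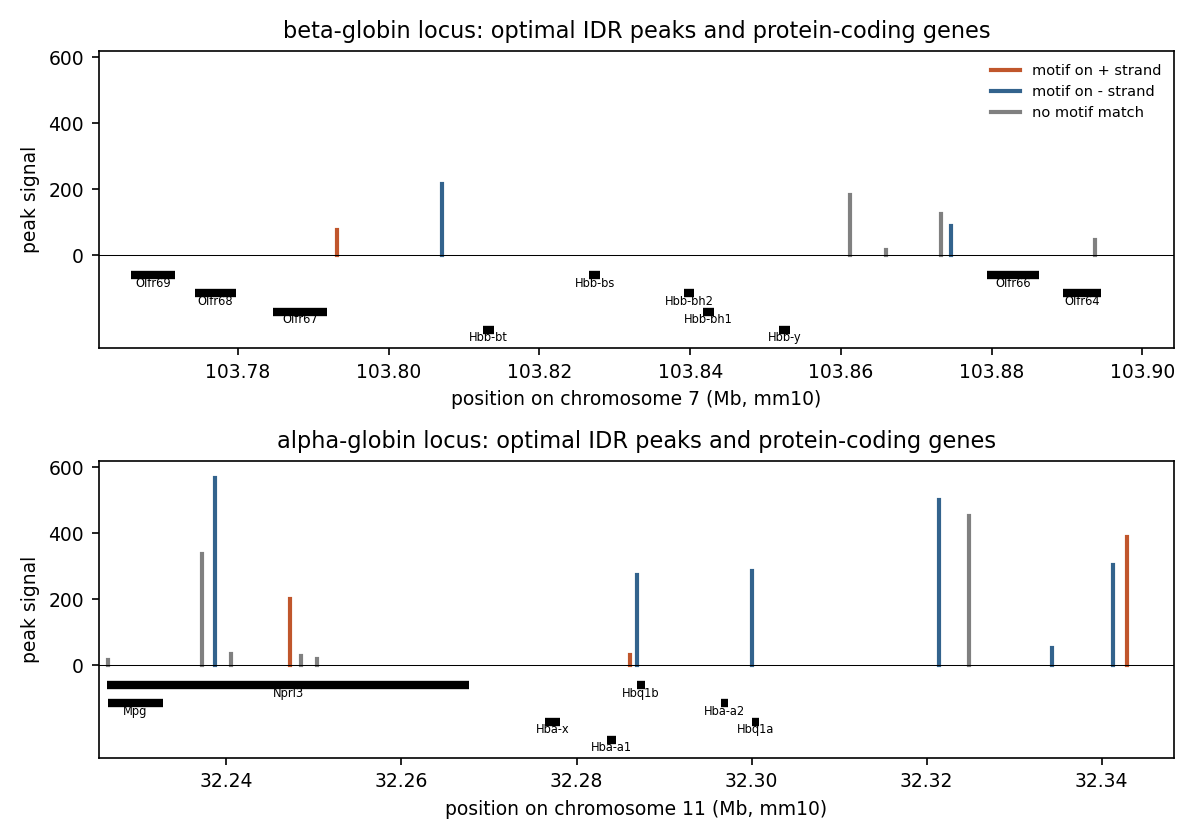
Map of the alpha-globin and beta-globin loci on mm10 (position in Mb, horizontal axis) with protein-coding genes as black boxes and optimal peaks as lines of the height of their signal (vertical axis), coloured by motif strand and grey without a match. The alpha-globin locus held 15 peaks with a highest signal of 567, and the beta-globin locus 7 with a highest signal of 218.

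Among loci of red cell transcription factors, the Gata1 locus held 13 peaks, or 109 per Mb, the Lmo2 locus 11, or 88.8 per Mb, and the Tal1 locus 8, or 69.4 per Mb. Within the 20 kb flank these counts were 3, 6 and 5, or 51.0, 93.9 and 90.4 per Mb. The strongest peak around Tal1, 2933 bp upstream of a start of the neighbour Pdzk1ip1, had a relative signal of 8.22 ± 2.10 (SD, n = 2). Near Bcl11a, a regulator of globin switching, the strongest peak reached 8.42 ± 2.25 (SD, n = 2), and near Runx1, a factor of blood stem cell formation, 7.15 ± 1.62 (SD, n = 2). The Runx1 locus held 8 peaks, or 24.6 per Mb, but 13 in the conservative list and 14 without replicate 2. The Kit locus, for the receptor of stem cell factor, held 2 peaks, or 11.0 per Mb, with the stronger at 1.55 ± 0.883 (SD, n = 2) in an intron of Kit.

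Hepatocyte loci ranged widely. Around Apoa1 to Apoa5, apolipoprotein genes, lay 13 peaks, or 90.7 per Mb, and around the fibrinogen genes Fga, Fgb and Fgg lay 6, or 42.2 per Mb. Within the 20 kb flank the Apoa1 to Apoa5 locus held 6. The Alb-Afp locus, for albumin and alpha-fetoprotein, held 1 peak, 600 bp upstream of a start of Afp, with a relative signal of 3.60 ± 0.587 (SD, n = 2), and 2 peaks in the conservative list and without replicate 1. The Serpina1 locus held 4 peaks, or 19.5 per Mb, and 1 within the 20 kb flank.

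Imprinted and developmental loci held between 4 and 32 peaks. The Igf2-H19 locus held 10, or 6 within the 20 kb flank. Its strongest peak lay at the 5' UTR of Mrpl23, beyond that flank, at 3.26 ± 0.670 (SD, n = 2). Upstream of H19, in the area where its imprinting control region is known to lie, peaks stood at 2170, 2628 and 3863 bp from the H19 start, which were picked out after their values were seen. None of these peaks had a match with at most 2 mismatches, so sites further from the motif as written would be missed. The relative signals of these peaks were 1.38 ± 0.505, 1.39 ± 0.123 and 0.686 ± 0.440 (SD, n = 2). The Kcnq1 locus held 19 peaks, Dlk1-Meg3 7, Hoxa 9, Hoxb 13, Hoxc 4, Hoxd 8 and the clustered protocadherins 32. The strongest peak of the protocadherin locus lay in an intron of Diaph1, beyond the 20 kb flank, at 7.26 ± 2.18 (SD, n = 2). The Myc locus held 5 peaks with the strongest 1965 bp upstream of a Myc start, the Gata2 locus 6, or 2 within the 20 kb flank, the Bcl11a locus 11 and the Xist-Tsix locus 7, whose strongest lay in an exon of Xist. Loci were not tested, and 127 of the 219 peaks were above the median signal of the optimal list.

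Peaks on X had lower signal than those on the autosomes. The median signal of the 1097 X peaks was 56.5, against 68.4 for autosomal peaks, a ratio of 0.827, below the 0.908 to 1.09 of random draws (permutation p = 0.002, the smallest that 1000 draws can give). Replicate 1 gave a ratio of 0.868 and replicate 2 a ratio of 0.810, or 0.839 ± 0.0411 (SD, n = 2). Single autosomes ranged from 0.929, on chromosome 13, to 1.08. X also held 6.71 peaks per Mb outside assembly gaps, against 14.8 to 34.2 on single autosomes. How much of each chromosome reads can be placed on was not measured.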

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

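These values were looked at without a test. The optimal list held 21 peaks on 6 scaffolds that are not placed on a chromosome, which no comparison used. They are listed because their number is above the 3 that a count of 0 allows, which says only that such peaks are present. They made up 0.0413% of the optimal list, with a median signal of 24.8 and a highest signal of 507.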

How the results depend on the processing

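The alternatives chosen after the data were seen are those without peaks ranked beyond 100000, with 1 transcript start per gene, and with motif-matched peaks only. Of 63 alternative values of the main results, 51 were kept and 12 moved, where kept means the same direction and side of the threshold for a tested value, within 1.5 times for a count, and within the error for any other. Among 362 alternative values of single lists, loci and peaks, 307 were kept, 30 moved, 10 lost and 6 gained a call, and 9 reversed. Of the 307, 79 were of lists and 91 of loci, and the rest were of single peaks. For single peaks the error is the SD of the same replicate values that were judged. Being kept was thus nearly fixed in advance and says little about their stability. Lists past the threshold numbered 4 to 8 with 1 replicate left out, and 1 with motif-matched peaks only. Promoter share ran from 17.7% to 23.2%, intergenic share from 32.2% to 35.8%, motif share from 65.1% to 74.4% and the X ratio from 0.810 to 0.868 with 1 replicate left out. Other settings moved these further with the call kept: promoter share was 15.1% with a 500 bp and 42.4% with a 5 kb window, motif share 39.9% with at most 1 and 89.8% with at most 3 mismatches, the X ratio 0.70 for mean signal, and the convergent share 25.4% for neighbours 5 kb to 1 Mb apart. With 20 kb flanks the loci held 147 peaks. Of the peaks in the loci, 127 were above the median signal, a count that is lower by construction. Shared peaks were 75.1% within 50 bp, 80.2% within 200 bp, 81.2% by any overlap, 84.6% with N divided by 2 and 52.2% with 2 times N, where N is the 50909 peaks taken from each replicate. Optimal peaks in the conservative list were 86.8% by any overlap. Spearman's rho was 0.870 in the conservative list, 0.850 within 50 bp and 0.839 within 200 bp. The 9 reversed list values were not past the threshold in the alternative: protocadherin genes at 41.1% without replicate 1 and 30.4% with 1 start; neuron and muscle genes at 37.5% without replicate 2, 8.33% with a 500 bp window and 25% with 1 start; other blood cell genes at 54.2% and Hox genes at 61.5% with a 5 kb window; hepatocyte genes at 20% and endothelial genes at 19% with motif-matched peaks only. The cause was not tested. Read depth is unknown, so what it limits was not measured.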

Other observations

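The test of X copies, the counts with 1 transcript start per gene and with motif-matched peaks only, the bounds over all subsets of the lists, and the windows, stretches and weak peaks described here were chosen only after the results were seen. The tests of motif share at equal GC content, of the 90th percentile of matched X peaks and of promoter GC content were added after a first round of tests, before their own values were seen.

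Peaks were unevenly spread along chromosomes. The densest 1 Mb window was on chromosome 10 at 80000001 to 81000000, with 145 peaks around genes such as Dot1l and Gpx4. The next, on chromosome 7 at 19000001 to 20000000, with Apoe and Foxa3, held 122. The longest stretch without a peak was on X at 24677647 to 35683501, with 9.28 Mb of sequence and 45 protein-coding genes, among them the Btbd35f family. On the autosomes the longest was on chromosome 1 at 144406825 to 149254351, with 4.85 Mb and the genes Brinp3, Rgs18 and Rgs21. Only assembly gaps were left out of these lengths. Sequence on which reads cannot be placed was not set apart, so a stretch without peaks need not lack CTCF.

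The optimal list also held 469 peaks ranked beyond 100000 in the pooled list, with a highest signal of 9.09. Of these, 78.5% (Wilson 95% interval 74.5 to 81.9) lay within 500 bp of a stronger optimal peak, against 1.67% of optimal peaks ranked 40000 to 50000, and 8.99% had a motif match.

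The strongest peaks of replicate 1 lay more at promoters and less often on the motif than those of replicate 2. At equal GC content, the promoter share of peaks of replicate 1 alone minus that of replicate 2 alone was 0.424 points (95% interval -0.789 to 1.71), against 25.7 points unmatched, so a difference in GC content between the libraries is a candidate explanation for the promoter share. It does not account for all of the motif share, which still differed by -16.0 points (95% interval -17.7 to -14.3), against -35.8 unmatched. Weak peaks near the rank limit are argued against as the whole explanation, since among the 20000 strongest peaks of each replicate the promoter share still differed by 3.8 points (95% interval 3.01 to 4.56), against 5.47 over all. Both libraries are of 1 biosample, so no biological explanation was tested.

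Promoters of heme synthesis, ribosomal protein and cohesin genes together had an odds ratio of 3.35 against other genes. With 1 start per gene it was 3.23 (95% interval 2.25 to 4.65), and within bins of promoter GC content, with 1 start per gene, 2.46 (95% interval 1.70 to 3.59). The lists were combined because they had passed the threshold. With an allowance for all 8192 subsets of the 13 lists, the lower bound was 1.40 with 1 start per gene and 1.02 within GC bins. The bound with 1 start argues against more starts as the whole explanation for the combined lists. The call of heme synthesis genes alone was lost with 1 start. The bound within GC bins is too near 1 to decide on GC content, since its error was estimated by resampling. The odds ratio was 2.09 (95% interval 1.42 to 3.08) with motif-matched peaks and 2.91 (95% interval 2.02 to 4.19) with peaks lacking a match. The share relative to other genes was 1.74-fold (95% interval 1.34 to 2.26) with motif-matched peaks and 2.07-fold (95% interval 1.68 to 2.54) with peaks lacking a match. With all peaks it was 1.84-fold (95% interval 1.60 to 2.10). Fewer genes held a motif-matched peak, 38 against 76, so the lost single calls do not decide for or against promoters recovered without the motif. That explanation is not excluded, since the intervals with and without a match overlap and the bound over all subsets was 0.855. No biological explanation was tested.

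Peaks on X had lower signal than autosomal peaks. Against autosomal peaks matched on location, motif mismatches and GC content, the ratio of medians was 0.895 (95% interval 0.808 to 0.985). The interval reaches the unmatched 0.929 of the lowest autosome but stays below equal medians, so these features may account for part of the lower median. As matched here, they do not account for the strongest peaks. There the matched ratio of 90th percentiles was 0.685 (95% interval 0.611 to 0.762), below the unmatched 0.856 of the lowest autosome. Other features of sequence and location were not matched. The unmatched ratio of 90th percentiles was 0.581 (95% interval 0.534 to 0.636) and that of medians 0.827, but the range for fewer X copies was set after related values were seen and the share of each sex in the pool is unknown, so this test does not decide whether copy number plays a part. Binding on the inactive X was not tested and stays open.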
